A study of Anopheles gambiae with 4 samples.

How the data were processed

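RNA was sequenced from salivary glands of female Anopheles gambiae, the African malaria mosquito, that were labelled infected or non-infected after blood feeding. The 4 libraries were 2 infected and 2 control libraries, and the sample labels place all of them at day 14, whereas the labels' extraction protocol describes dissection at day 7. Per the labels' protocols, total RNA came from pools of about 50 salivary glands, ribosomal RNA was depleted, and directional paired-end libraries were sequenced on an Illumina instrument. How the non-infected mosquitoes were fed is not given in the sources used here.

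Reads were assessed with FastQC 0.11.9 and quantified with Salmon 0.11.2, per the submitters' processing notes. Each deposited file gives, for one library, an estimated count of fragments per annotated transcript, in which fragments that fit several transcripts are divided among them, so that values need not be whole. Between 26.2% and 29.0% of the 15357 transcripts per library carried an estimated count more than 0.001 away from a whole number. The deposited TPM values are estimated counts divided by the effective transcript length and scaled to one fixed total per library, per the file headers. The deposited length and effective length in nucleotides were used to describe transcripts. The transcript set, genome build and bias options are not given in the sources used here. Dividing by an effective length gives very short transcripts a large share of TPM, so levels were compared on counts and TPM was used for shares of isoforms within a gene.

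Transcripts were assigned to genes by the identifier before the isoform suffix, giving 13460 genes. The files pair no names with these identifiers, and 0 of them matched the reference gene table of another assembly. The 31 lists of genes fixed before the data were examined, among them those of markers of other tissues, were defined by names. Identifiers planned for some lists counted only where the reference's name for them fitted the list. The lists held 0 matched genes and were therefore not tested. For the same reason no gene function or position is given and at most 2 identifiers per direction are printed for each comparison. Genes printed were those of smallest p in each direction, the fallback of a rule that named the genes past the threshold with the largest change. For isoform usage, the rule took genes past the threshold by the difference in isoform share.

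Estimated counts were summed per gene and rounded to whole numbers. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood fit with infection status as the term, Benjamini-Hochberg adjustment, threshold 0.05), and 9541 genes entered the test. Rounded transcript counts were tested in the same way (10909 transcripts). Isoform usage was tested with edgeR's diffSpliceDGE gene-level F test, which asks whether the isoforms of a gene change by different folds, in the 968 genes with 2 or more transcripts passing the filter. Standard errors of log2 fold changes were derived from the F statistic. The share of an isoform is its percent of the gene's TPM in a library. Estimated counts of isoforms carry an assignment uncertainty that the files do not give.

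Library totals were between 10211972 and 13504151 estimated counts, and the infected libraries were the shallower ones. Over all tested genes the median standard error of a log2 fold change was 0.24 and the median 95% interval reached 0.63 on either side, a fold of 1.55. The common coefficient of variation between replicates was 25.3%. The labels do not say whether replicates came from separate mosquito pools, so p-values measure only the spread between these libraries, which may be technical. Chi-square values per degree of freedom were 37.0 between the infected and 112 between the control libraries, so neither pair was one library under 2 labels. With 2 libraries per group no exact permutation test of a single value can go below 0.333 (two-sided). Floors of 3 counts cover counting error only.

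The tests were tried on simulated counts with the means and library sizes of these data and 200 changed genes. When the simulated spread followed the fitted trend, edgeR recovered 2% of genes changed 2-fold, 96.5% at 4-fold and 99.5% at 8-fold, DESeq2 recovered 9.5%, 96% and 99.5%, with 3, 10 and 8 false calls, and the usage test recovered 8.5%, 66% and 98.5%, with 3, 14 and 13 false calls. In a second setting the trend was multiplied per gene by a random factor, drawn with the prior degrees of freedom of the quasi-likelihood fit. That prior belongs to the quasi-likelihood dispersion and not to the trend, and the factor raises the mean spread above the trend. There edgeR recovered 0% at each of these folds, and DESeq2 recovered 8.5%, 76% and 91%, with 68, 81 and 108 false calls. The usage test in that second setting recovered 0% at 2-fold and 4-fold and 41.5% at 8-fold, with 9 false calls at 8-fold. In both settings isoform counts were drawn independently, without dividing reads among isoforms. The rates of the usage test therefore leave out errors of read assignment.

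Alternatives were RLE and upper quartile scaling, no filter or a filter of 10 CPM in 2 libraries, DESeq2 1.42.0, limma 3.58.1 (voom), an average transcript length offset, a test against a fold of 1.5, removal of the 20 genes with most counts, the replicate number as a block, and leaving out each library. The replicate number is shared between groups in the labels without a stated meaning, so it was an alternative and not part of the main model. Deviations of same-numbered libraries from their group means had a correlation of 0.0023 across 9541 genes, which gave no sign of pairing. The alternatives were fixed before the data were examined. Removing genes under 500 nt and combining DESeq2 with each left-out library were added afterwards.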

Results

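The series asked how transcription and alternative splicing in the malaria vector Anopheles gambiae relate to infection. The salivary glands are the tissue from which malaria parasites pass to the next host. Expression was measured in 2 libraries of glands labelled infected and 2 libraries of glands labelled non-infected (control). Infected glands here means glands with that label, and no measure of parasites in them was examined. Infected replicates 1 and 2 held 10446555 and 10211972 estimated counts, and control replicates 1 and 2 held 13504151 and 12722213. Between 12602 and 13201 of the 15357 listed transcripts had a count above 0 in a library. After thinning every library to 10211959 counts, 11239 and 11181 genes were detected in infected replicates 1 and 2, and 11548 and 11098 in control replicates 1 and 2.

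By TPM, a small number of short transcripts made up most of every library. AGAP029039, whose transcript is 297 nt long, held 26.3% and 26.7% of TPM in the infected replicates and 25.5% and 24.6% in the controls. AGAP029378, with a transcript of 331 nt, held 10.8%, 8.88%, 11.0% and 11.3% in the same order. The 10 genes of highest mean TPM together held 62.5% and 65.7% of TPM in the infected libraries and 62.8% and 61.5% in the controls. Log2 fold changes of these 10 genes between infected and control ranged from -0.20 to 0.67, and the smallest adjusted p among them in edgeR's quasi-likelihood test was 0.789. Transcripts under 500 nt took 63.9% to 69.7% of TPM but 20.3% to 24.3% of counts. By counts, the gene with most counts held 7.24% to 8.96% of a library and the 20 genes with most counts held 35.2% to 42.0%. Those under 200 nt took 1.13% of counts in infected replicate 2 and 0.840% in control replicate 1, against 0.601% in infected replicate 1 and 0.614% in control replicate 2, so that this share differed within each group.

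Similarity between infected and control libraries overlapped with that between replicates. Across 9541 genes, Pearson's correlation of log2-CPM was 0.971 between the infected replicates and 0.961 between the controls. The 4 correlations between an infected and a control library were 0.973, 0.972, 0.956 and 0.954. Genes are not independent replicates, so these values describe the libraries. The first principal component (43.3% of variance) placed infected replicate 2 at -38.1 and control replicate 2 at 28.0, with infected replicate 1 at -1.40 and control replicate 1 at 11.5. The second component (37.7%) parted control replicate 1 at -35.1 from control replicate 2 at 27.2.

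**Figure D1:**
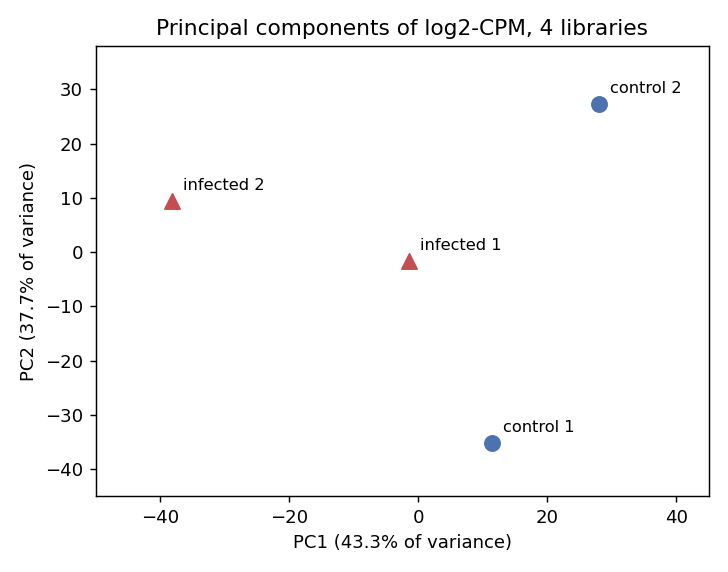
Principal components 1 (x axis) and 2 (y axis) of log2-CPM over 9541 genes, in units of component score, with controls as blue circles and infected libraries as red triangles. Infected replicate 1 lies near the origin at -1.40 on component 1, and control replicates 1 and 2 lie at -35.1 and 27.2 on component 2.

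The first comparison asked which genes differed in level between infected and control glands. Lower values in infected glands stood out for AGAP004581, a gene with 1 listed transcript of 1215 nt. It had 10.9 ± 2.56 CPM in infected and 84.3 ± 1.84 CPM in control libraries (SD, n = 2), a 7.73-fold difference. AGAP004582, with a transcript of 507 nt, had 2.67 ± 0.104 CPM in infected and 11.5 ± 1.97 CPM in control libraries. Among genes with higher values in infected glands, AGAP000311 (2294 nt) had 18.5 ± 4.23 CPM against 4.94 ± 0.315 CPM in controls, a 3.74-fold difference. AGAP012916 (915 nt) had 4.88 ± 0.865 CPM against 0.920 ± 0.158 CPM. For each of these 4 genes both infected libraries lay on one side of both controls. The genes were picked by smallest p, so this is no separate support for them. Of the 9541 tested genes, 3636 (38.1%) were parted in this way, where chance gives 33.3%. The other divisions of the 4 libraries, 2 against 2, parted 29.5% and 32.4%.

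No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. At an unadjusted p of 0.05, 499 of 9541 genes passed, 265 with higher and 234 with lower values in infected glands, where chance alone gives 477 and the other 2 divisions of the 4 libraries, 2 against 2, gave 289 and 430. AGAP004581 had a log2 fold change of -2.95 (SE 0.22) with an edgeR adjusted p of 0.658, and AGAP004582 one of -2.11 (SE 0.23) with an edgeR adjusted p of 0.787. The edgeR log2 fold changes of AGAP000311 and AGAP012916 were 1.90 (SE 0.23) and 2.40 (SE 0.34), each with an adjusted p of 0.787. DESeq2, the alternative count model, called 19 genes, of which 11 rose and 8 fell in infected glands. In DESeq2, AGAP004581 fell by 2.97 on the log2 scale (SE 0.33, adjusted p = 2.24e-15), AGAP004582 fell by 2.13 (SE 0.45, adjusted p = 0.00339) and AGAP000311 rose by 1.89 (SE 0.41, adjusted p = 0.00339). The genes that rose in DESeq2 had log2 fold changes between 1.24 and 5.09, and those that fell had values between -2.97 and -1.47. The rise of 5.09 rested on infected replicate 2, with 215 normalized counts against 5.37 in infected replicate 1 and 1.55 and 5.05 in the controls, and the next largest rise was 2.04. AGAP012916 was given no adjusted p by DESeq2 (log2 fold change 2.40). Leaving out a library sets 1 library against 2, so that the spread comes from the group of 2 alone and a lost call does not show that a gene did not differ. Of the 19 genes, 2 were called by DESeq2 without each library in turn, among them AGAP004581 (largest adjusted p = 0.000117). AGAP004582 had a DESeq2 adjusted p of 0.373 without control replicate 1 and 0.99997 without infected replicate 2, and DESeq2 gave it no adjusted p in the other 2 of these fits. AGAP000311 had a DESeq2 adjusted p of 0.0442 without control replicate 2, 0.101 without control replicate 1 and 0.99997 without infected replicate 2, and none without infected replicate 1. In simulated data whose spread varied between genes around a raised mean, edgeR recovered 0% of 8-fold changes and DESeq2 91%, with 108 false calls. Where the simulated spread followed the fitted trend, both recovered 99.5%, with 5 false calls by edgeR and 8 by DESeq2. The 108 false calls exceed the 19 calls made here, and the spread of neither setting was checked against these libraries. The count of 0 therefore sets no limit on 8-fold changes, and the count of 19 can hold false calls.

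**Figure D2:**
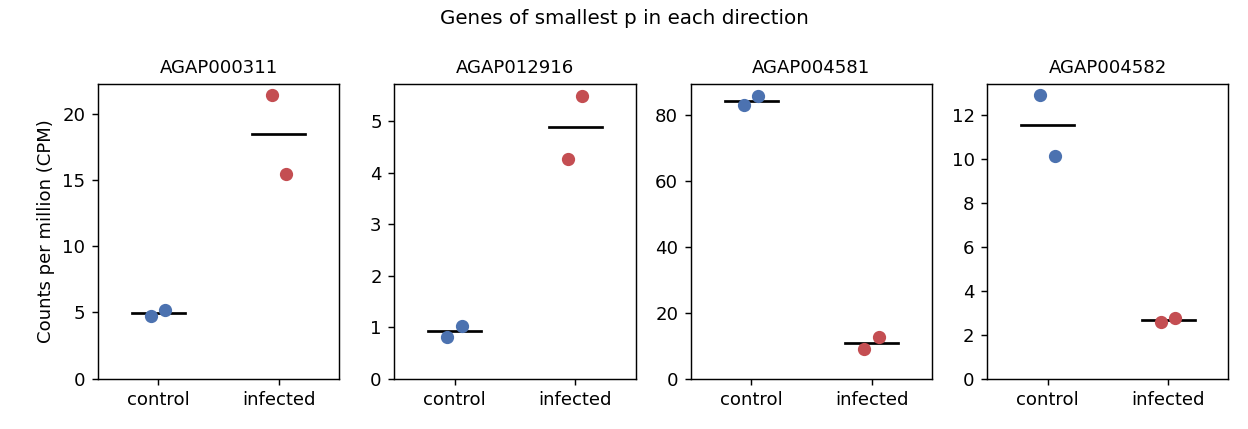
CPM (y axis, linear from 0) of the genes of smallest p in each direction, by group (x axis). Points are libraries and the black line is the mean of 2. AGAP004581 lies at 9.10 and 12.7 CPM in infected and at 83.0 and 85.6 CPM in control libraries.

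Gene classes by transcript length and isoform number had median log2 fold changes between -0.03 and 0.16. The 45 tested genes whose longest transcript is under 200 nt had a median log2 fold change of 0.16, but their median deviation from the mean of the 4 libraries was -0.36 in infected replicate 1 and 0.53 in infected replicate 2. The 222 genes of 200 nt to under 500 nt, the 4416 genes of 500 nt to under 2000 nt and the 4858 longer genes had median log2 fold changes of -0.01, 0.04 and -0.02. Genes with 2 or more annotated transcripts (1170 tested) had a median of -0.03, and the 8371 genes with 1 transcript a median of 0.02. These classes were chosen after the data were seen and were described, not tested.

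At the level of single transcripts, 0 of 10909 passed edgeR's quasi-likelihood test, with a smallest adjusted p of 0.825. At an unadjusted p of 0.05, 560 transcripts passed where chance gives 545 and the other 2 divisions gave 338 and 466. DESeq2 called 20 transcripts that rose and 21 that fell in infected glands.

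The second comparison, the one named by the title of the series, asked whether isoforms of a gene changed in proportion. The usage of isoforms differed between groups in 5 of 968 genes by edgeR's gene-level usage test. In AGAP011310, isoform RB (1151 nt) held 53.1% ± 0.067 of the gene's TPM in infected libraries (SD, n = 2) and was listed at 0 in both controls, where isoform RA (1200 nt) held 100%. In AGAP010194, isoform RB (1564 nt) held 39.7% ± 6.11 in infected libraries and was listed at 0 in both controls. In AGAP011583, isoform RA (8815 nt) held 10.1% and 5.36% in controls and was listed at 0 in both infected libraries. In AGAP002358, isoform RA (1301 nt) held 4.49% and 5.54% in controls and was listed at 0 in both infected libraries. In the fifth gene, the isoform with the largest difference held 82.8% ± 7.21 in infected and 71.3% ± 5.05 in control libraries, and another isoform (RD) held 10.6% and 8.60% in controls and was listed at 0 in both infected libraries. All 5 genes thus had an isoform at 0 in both libraries of one group (with 10 or more counts in the other), as did 22 of the 968 tested genes.

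**Figure D3:**
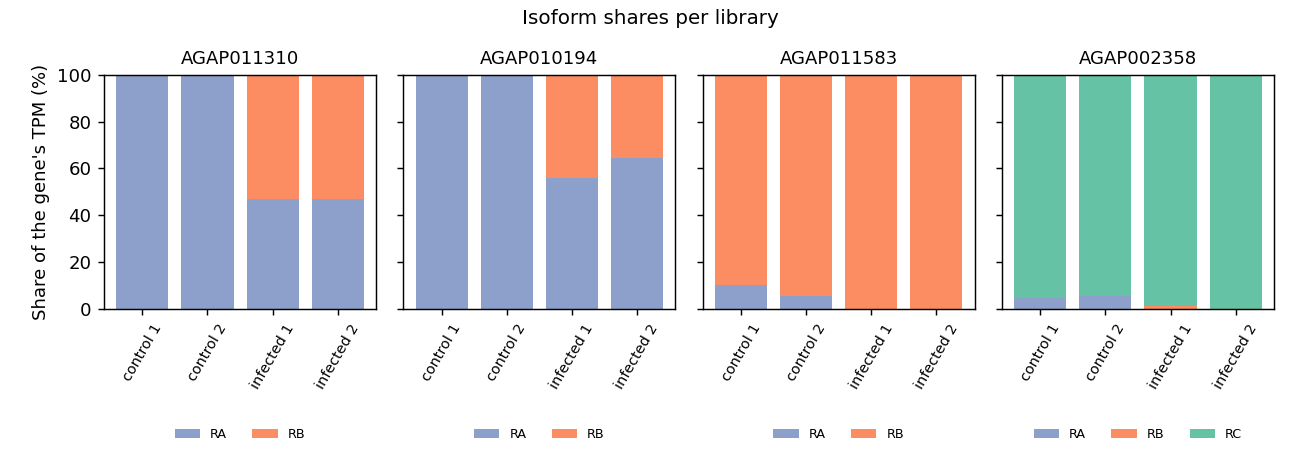
Share of a gene's TPM held by each isoform (y axis, percent, stacked) in each library (x axis) for 4 of the 5 genes past the usage threshold. In AGAP011310 isoform RB takes 53.2% and 53.1% in the infected libraries and is at 0 in both controls, while in AGAP002358 isoform RA takes 4.49% and 5.54% in the controls and is at 0 in both infected libraries.

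The adjusted p of the usage test (edgeR) was 0.0287 for AGAP011310 and AGAP002358 and 0.0495 for AGAP010194, AGAP011583 and the fifth gene. Counts behind these shares were 170 and 200 for AGAP011310 in the controls, where 3 counts are 1.76% and 1.5% of the gene, and 78 and 69 for AGAP010194, where they are 3.85% and 4.35%. At an unadjusted p of 0.05 the usage test passed 77 genes, where chance gives 48.4 and the other 2 divisions of the 4 libraries gave 61 and 70. No call held when the transcripts were tested singly and combined per gene (Simes, smallest adjusted p = 0.0644, edgeR), where the other 2 divisions gave 1 and 9 genes. With any 1 of the 4 libraries left out the test called 0 genes, but it then has 1 library in a group, and whether it can call genes at that size was not tested. At the adjusted threshold, the other 2 divisions gave 5 and 12 genes by the usage test, so that the count for infection did not exceed them.

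Most genes kept one leading isoform across the libraries. Of 1245 genes with 2 or more annotated transcripts, 1105 had at least 20 counts in every library, and 867 of these had the same leading isoform in all 4. The leading isoform held a median of 75.8% and 76.0% of TPM in the infected and 75.0% and 77.3% in the control libraries. The mean effective number of isoforms per gene was 1.66 in both infected libraries and 1.69 and 1.64 in the controls. The leading isoform differed between the infected replicates in 114 genes and between the controls in 143 genes, and between an infected and a control library in 124 to 143 genes. It was one isoform in both infected libraries and another in both controls in 23 genes, against 16 and 19 genes for the other divisions of the 4 libraries. The mean absolute difference in isoform share was 7.82 percentage points between infected replicates, 8.06 between controls and 7.75 to 8.44 between groups.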

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

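DESeq2 was the planned setting that changed the counts of 0 genes and transcripts: it called 11 genes higher and 8 lower, and 20 transcripts higher and 21 lower, in infected glands. Under every other planned setting run, the counts stayed at 0, with smallest edgeR or limma adjusted p for genes from 0.162 to 0.9999. With DESeq2 and 1 library left out, a choice made after seeing the data, the genes higher and lower numbered 12 and 59 without infected replicate 1, 0 and 2 without infected replicate 2, 20 and 98 without control replicate 1, and 50 and 42 without control replicate 2, and 8, 2, 9 and 10 of the 19 genes were called in these fits, each of which has 1 library in a group. The log2 fold changes of the 4 named genes kept their direction in every setting in which they were tested. Of the 5 usage calls, all were kept with RLE scaling and among the 7 calls of limma diffSplice, and with isoforms of at least 5% share (1 call) 1 was kept of the 3 that could still be tested. The usage count was 0 by Simes, 0 without a low-count filter, and 0 without each library in turn, which leaves 1 library in a group. With the labels' number as a replicate block, which the check did not show to pair the libraries, the counts were 0 higher genes, 0 lower genes and 0 usage genes, and the block leaves 1 residual degree of freedom. The causes of these changes were not tested. The tests of gene lists and tissue markers were not run because no gene could be matched by name. Depth limits the shares that can be told from 0, as 3 counts are up to 5.66% of a called gene in a library.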

Other observations

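Except for the count of calls at equal depth, the tests here were chosen after the results they bear on had been seen. Neighbouring identifier numbers behaved alike to a small degree: over 6916 pairs of tested genes with consecutive numbers, the log2 fold changes for infection had a Spearman correlation of 0.091 across genes. The other divisions of the libraries gave 0.102 and 0.078, so this was not particular to infection.

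The 3 genes of smallest p among those lower in infected glands have consecutive identifier numbers, with edgeR log2 fold changes from -2.95 to -2.11 and adjusted p from 0.658 to 0.787. DESeq2 called all 3. All 3 carry non-whole estimated counts, so reads are shared with other transcripts. All 3 were lower, so reads merely divided differently among them do not account for the pattern. Their summed CPM was 20.1 and 30.5 in infected and 172 and 164 in control libraries, a log2 ratio of -2.73. That sum had to fall because each gene was picked as lower, so it is no separate test. Whether reads went to transcripts outside the 3 was not tested and stays open. That neighbouring numbers move together in any split remains open, since 6 runs of 3 consecutive numbers had changes beyond 1 one way for infection and at most 6 in another split. The smallest change within the run of largest changes was 2.11 for infection and 2.30 and 1.63 in the other splits. Infection, and handling or timing of dissection that differed between groups, stay open and untested, and may each contribute to the -2.73.

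A response to infection is one hypothesis for the 19 DESeq2 calls, and no test here decides it. Of the 3 splits of the 4 libraries, 1 (the real one) gave as many, with 19 calls against 0 at most in another, and 3 splits are too few for a share under 0.05. The other splits gave 0 calls together, but each puts an infected and a control library on both sides. A difference between infected and control libraries would widen the spread within those sides and hold calls down. The 0 therefore does not decide whether DESeq2 puts the spread too low, and DESeq2 made false calls on simulated data. With all libraries thinned to 10211959 counts, 13 of the 19 were called, between the under 10 set in advance for an effect of the greater depth of the control libraries and the 15 set to exclude one, so depth stays open. The 6 genes that lost their call had adjusted p from 0.0415 to 0.0491 before and from 0.0764 to 0.106 after thinning, and their median SE went from 0.443 to 0.456. Their log2 fold changes moved by at most 0.129, but thinning by itself leaves folds in place on average, so this does not decide it either. DESeq2 also sets in each fit how many genes it adjusts for, 7771 before thinning. A call lost on thinning therefore need not reflect depth, and the count of 13 does not isolate it.

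The 5 isoform usage calls may reflect how the quantifier assigns reads. Isoforms at 0 in both libraries of one side and at 20% or more in both of the other numbered 9 for infection and at most 10 in another split, a count that covers 2 of the 5 genes. Tested genes with an isoform at 0 on one side and 10 or more counts on the other, which covers all 5, numbered 22 for infection and 21 in each other split. Such isoforms thus occur about as often without infection as the dividing line, and isoforms estimated at exactly 0 by the quantifier are a candidate explanation. All 3 splits gave at least 5 calls, the highest other being 12, and 3 splits cannot give a share under 0.05. The split with 12 calls put infected replicate 1 with control replicate 2, which also shared the lower counts of transcripts under 200 nt and whose deposited files carry a common number that the labels do not explain. That pair holds 1 library per group, so no test within it was possible, and a usage test with the file number as a block was not run. Deviations of the 2 controls from their mean are equal and opposite. The correlation of deviations across genes thus has the same size for this pair, 0.0023. Over all 9541 genes it gave no sign of a shared batch, but short transcripts were alike within the pair. Transcripts under 500 nt held 63.9% of TPM in infected replicate 1 and 64.1% in control replicate 2. They held 69.3% in infected replicate 2 and 69.7% in control replicate 1. A shared batch in gene levels therefore stays open. The correlation does not cover isoform shares, for which a shared batch and a real change of isoforms stay open.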
